A study of Arabidopsis thaliana with 8 samples.

How the data were processed

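Total RNA from germinating Arabidopsis thaliana seedlings was labelled with biotin and hybridised to 1-colour oligonucleotide arrays, 1 array per sample. Per the labels' protocols, seeds were kept at 4 °C for 4 days and then germinated for 2 days at 23 °C, under 16 h of light and 8 h of dark, on MS medium with 2% sucrose, with or without 0.5 uM abscisic acid. cDNA was made from 16 ug of total RNA, and 30 ug of labelled cRNA went onto each array. The deposited values are log2 expression values, 1 per probe set and array, and per the submitters' processing notes they were made with RMA, a method that corrects background, quantile-normalizes the arrays and summarises the probes of a set; its version and the array software are not given in the sources used here. The table held 22246 probe sets, with 0 control probe sets and 0 columns left unused. Array medians lay between 5.91 and 5.97, and no pair of arrays held identical columns.

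Groups and replicate numbers were taken from the sample titles. The free-text descriptions of all 8 samples repeat the wording for untreated wild type and contradict the titles, source names and treatment protocols of 6 of them, so they were not used. Nothing in the labels says that the 2 arrays of a group came from separate cultures. P-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision of every value.

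The deposited log2 values were used as they stand, without a filter. limma 3.58.1 in R 4.3.3 fitted group means to all 8 arrays, so that the 4 groups share 1 estimate of the spread per probe set with 4 residual degrees of freedom, followed by empirical Bayes moderation. Each of 4 contrasts was tested with two-sided p-values adjusted by Benjamini-Hochberg, and a probe set was called at an adjusted p below 0.05. Standard errors are those of the fit. The replicate number is not in this fit, so shifts between numbers 1 and 2 enter the spread and tend to make p-values too large. The median SE was 0.277, against 0.178 with the number as a block. A count of 0 calls is therefore not evidence that a mutation has no effect. In simulated data with the same residual spread, this test recovered 76% of changes of 3 on the log2 scale in the ABA contrast, 77% for ahg1-1, 65% for ahg3-1 and 71% for ahg1-1 against ahg3-1, each over 22246 probe sets. Of changes of 1 it recovered 1% in the ABA contrast and 0% in the other contrasts, with 0 false calls. With the replicate number as a block it recovered 46%, 22%, 34% and 28% of changes of 1 in the same order of contrasts. Of changes of 3 the block recovered 91% to 95%, with 3 to 6 false calls per contrast.

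Probe sets were named from the platform annotation, through the gene identifiers of the TAIR10.1 gene table. 13072 probe sets had 1 gene, 12998 of them found in the gene table, while 503 had several genes and were not named. The remaining 8671 probe sets are unnamed here. Of 278 list entries written down before the data were examined, 5 were left out because the gene table pairs the locus with other symbols, and 53 had a named probe set. The lists of clade A PP2C phosphatases, ABA receptors, seed maturation regulators, ABA synthesis and breakdown, heat shock and endosperm markers had 0 such members and are not analysed here. AHG1 and AHG3 themselves belong to these, so the mutant labels were not checked against the mutated genes.

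Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 between genes, 1 probe set per locus (the one with the highest mean), and adjusted over the 7 lists tested within each contrast. An estimated correlation between genes was used as an alternative. The covariance of changes across probe sets is given beside the mean of 100 simulated data sets with no effect and the same shared arrays. Simulated values were drawn independently for each probe set and array. Correlation between genes and between same-numbered arrays was left out, so the simulated values vary less than chance values would and are no test.

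The rule for named genes was fixed before the data were examined. It takes AHG1 and AHG3, the 8 probe sets per direction with the largest change among called probe sets with 1 gene and no overlap between the groups' arrays, and per list up to 3 called members with the largest change or, with none called, the member with the smallest unadjusted p. Genes named outside this rule are said to have been chosen after their values were seen: these are up to 6 per direction in the mutant contrasts, with the same direction in both replicate numbers and no overlap between the groups' arrays, and the probe set with the largest change. Expansin genes of the cell wall list in the ABA contrast and the LEA gene M10 were also named after their values were seen. Lists with 3 measured members are named in full with ABA. Differences within a replicate number are differences between 1 array and 1 other, with no test.

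Alternatives were an intensity trend in the moderation, leaving out probe sets below the 40th percentile of the mean, cyclic loess, median centring, only the 4 arrays compared, only probe sets with 1 gene, the replicate number as a block, a minimum change of 1 on the log2 scale, and leaving out each array in turn.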

Results

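Gene expression was compared in germinating seedlings of the Columbia wild type and of the ahg1-1 and ahg3-1 mutants, whose mutations lie in related but separate genes for protein phosphatases of the PP2C class. Abscisic acid (ABA) is a plant hormone that delays germination, and PP2C phosphatases of this kind are negative regulators of its signalling. The 8 arrays formed 4 groups of 2: wild type without ABA, and wild type, ahg1-1 and ahg3-1 on 0.5 uM ABA, all collected 2 days after transfer from the cold. Values are log2 expression for 22246 probe sets. The arrays also differed by replicate number, 1 or 2, across all 4 groups: deviations from the group means of same-numbered arrays correlated across probe sets with r between 0.50 and 0.84 in the 6 pairs of groups. Differences within each number are therefore given for the called lists and for some of the genes.

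The first comparison set wild-type seedlings with ABA against those without it. Both were collected at the same time, so rose and fell mean higher and lower with ABA. ABA delays germination, so a difference in the stage of germination cannot be told apart from an effect of ABA on these genes. LEA and storage protein genes were among those with the largest rises. AT1G04560, which encodes an AWPM-19-like membrane protein, rose from 5.47 ± 0.28 without ABA to 12.27 ± 0.34 with it (log2, mean ± SD, n = 2), a log2 change of 6.80 ± 0.24 (SE) or 112-fold (limma, adjusted p = 0.00042). AT2G28490, a vicilin-like storage protein, rose by 6.73 ± 0.50 and AT3G17520, a late embryogenesis abundant (LEA) protein, by 6.67 ± 0.50, both at an adjusted p of 0.0036. The genes with the largest falls included several of the photosynthetic machinery: PSAN, a subunit of photosystem I, fell from 11.67 ± 0.34 to 6.92 ± 1.53, and PRK, the phosphoribulokinase of the Calvin cycle, from 10.998 ± 0.042 to 7.43 ± 1.28 (n = 2 each; limma, adjusted p = 0.029 and 0.041). In the 8 fits that leave out 1 array the call of PSAN held in 2 and that of PRK in 1.

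In all, 305 probe sets passed the test, 154 higher and 151 lower with ABA, and each of the 305 changed at least 2-fold. Among the other named genes that rose were LEA18 (6.31 ± 0.93), the papain-type cysteine protease gene AT3G54940 (6.26 ± 0.31), the LEA genes AT4G36600 (6.24 ± 0.81) and AT4G21020 (6.10 ± 0.63), and the vicilin-like PAP85 (6.01 ± 0.85), with adjusted p between 0.0011 and 0.033. AT3G05730, which encodes a defensin-like protein, fell by 5.10 ± 0.50, from 9.72 to 4.62. The jacalin-type lectin AT1G52070 fell by 3.72 ± 0.31, the small photosystem II protein AT1G51400 fell by 3.82 ± 0.60, the rhodanese-domain protein AT2G42220 fell by 3.66 ± 0.54, the lipid transfer-like AT5G48490 fell by 3.64 ± 0.59 and the methionine sulfoxide reductase MSRB6 fell by 3.13 ± 0.38, with adjusted p between 0.0057 and 0.045.

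LEA proteins, which protect cell structures of the dry seed, were the largest measured list with a change. Of 16 measured members 12 rose, 0 fell and 4 did not pass; all 16 rose when adjusted over the list alone. The median log2 change was 5.69, with members from 0.88 (M10, not called) to 6.67, and it was 5.0025 within number 1 and 5.77 within number 2. All 3 measured seed storage and oil body genes rose, with OLEO3, an oleosin of the oil body surface, at 5.36 ± 0.30 beside AT2G28490 and PAP85; their medians were 5.20 and 7.32 within numbers 1 and 2. In the photosynthesis list 3 of 9 members fell (PSAN, PRK and ATPC1, a subunit of the chloroplast ATP synthase, which fell by 1.66 ± 0.25), 0 rose and 6 did not pass; all 9 fell when adjusted over the list alone. With the replicate number as a block 15 of 16 LEA genes passed as higher and all 9 photosynthesis genes as lower over all probe sets. The photosynthesis median was -3.57, at -2.38 within number 1 and -4.55 within number 2. It ran from -4.82 to -2.06 when 1 array was left out. By camera with a preset correlation the adjusted p was 2.1e-28 for the LEA list, 3.0e-09 for storage and oil body and 2.2e-13 for photosynthesis. With an estimated correlation none of these held, with an adjusted p = 0.076 for the LEA and storage lists and an adjusted p = 0.12 for photosynthesis.

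**Figure D1:**
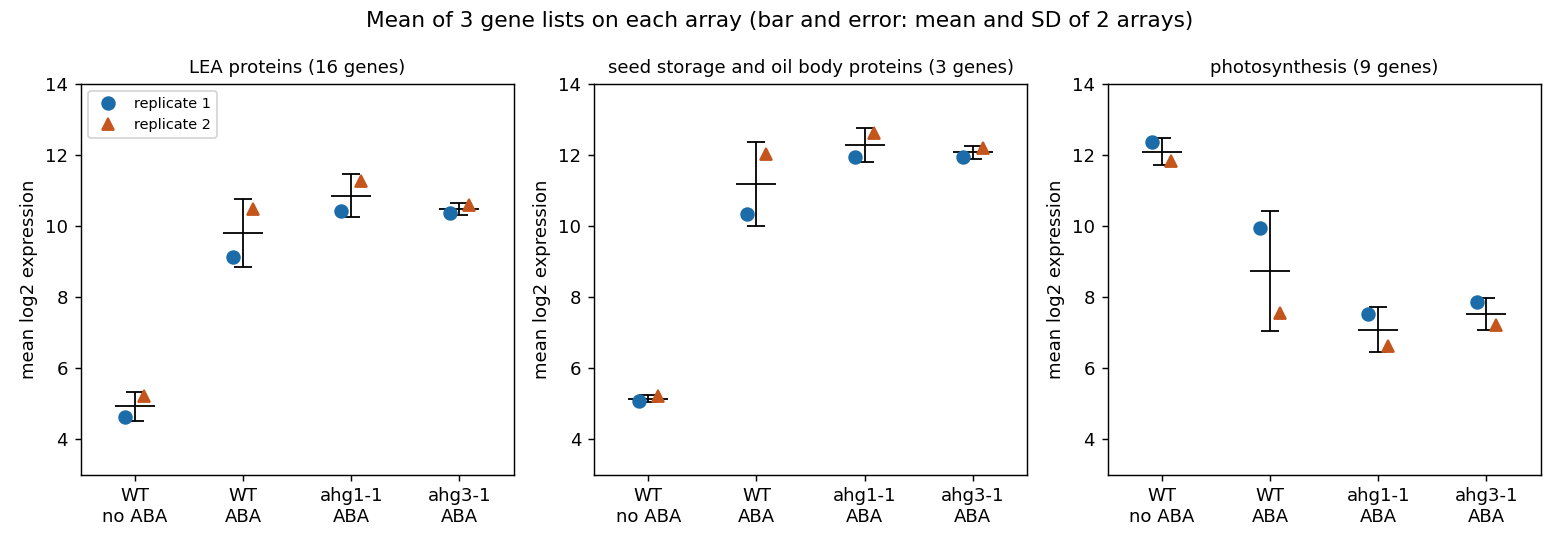
Mean log2 expression of the members of 3 gene lists (vertical axis) on each of the 8 arrays, by group, with replicate 1 as circles, replicate 2 as triangles, and the mean and SD of the 2 arrays as a bar with an error bar. LEA genes averaged 4.92 without ABA and 9.80, 10.85 and 10.47 in wild type, ahg1-1 and ahg3-1 on ABA; photosynthesis genes averaged 12.08, 8.73, 7.08 and 7.53 in the same order.

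Members of the list of cell wall loosening genes stood on both sides. The expansin genes named here were chosen after their values were seen. The expansin genes EXPA20 (1.90), EXPA15 (1.62), EXPA9 (1.49) and EXPA4 (1.03) had higher values with ABA, and EXPB3 (-2.46), EXPA8 (-2.07) and EXPB1 (-1.44) lower ones, each with the same direction within both numbers. None of the 10 members passed over all probe sets, the lowest p belonging to the xyloglucan endotransglucosylase XTH33 (-0.97 ± 0.18, limma, adjusted p = 0.065); adjusted over the list alone, 4 were higher and 3 lower. With the replicate number as a block EXPA20, EXPA15, EXPA9 and EXPA4 passed as higher over all probe sets, and EXPB3, EXPA8, EXPB1 and XTH33 as lower (limma, adjusted p between 0.0014 and 0.033). The list had a median of -0.07 (camera, adjusted p = 0.87). The 3 measured ABA-induced stress genes did not pass either: COR15A differed by 1.11 ± 0.29, COR15B by -0.20 and COR47 by -1.16, the last at 0.24 within number 1 and -2.56 within number 2 (list adjusted p = 0.92). EEL, a bZIP factor of the ABA pathway, differed by 2.02 ± 0.43 (limma, adjusted p = 0.098). With the block EEL and COR15A passed (limma, adjusted p = 0.00092 and 0.012). The gibberellin receptor genes GID1A, GID1B and GID1C had a list median of 0.17 (adjusted p = 0.92), and the fatty acid breakdown genes SDP1, AIM1 and ICL one of 0.47 (adjusted p = 0.21). AUR1 of the cell division list differed by -0.48 ± 0.28, the root hair expansin EXPA18 by -0.79 ± 1.08 and the seed coat gene BAN by 0.19 ± 0.38, all above the threshold. EXPA18 stood at 0.72 within number 1 and -2.30 within number 2, and BAN at -0.06 and 0.45. Few members of such lists were measured: 2 of 27 for cell division, 2 of 7 for root hair, 1 of 5 for seed coat and 1 of 13 for the list of EEL. The stress list had 3 of 22, and the gibberellin and fatty acid breakdown lists 3 of 18 each. The values of these members do not describe the lists as wholes.

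The count of called probe sets depended on single arrays. It was 388 without wild type on ABA replicate 1, 51 without the first and 116 without the second wild-type array on no ABA, 80 without wild type on ABA replicate 2, 108 without either ahg1-1 array and 112 without either ahg3-1 array, and it was 33 when only the 4 wild-type arrays were fitted. Of the 8 fits without 1 array, the calls of AT4G36600, AT1G51400, AT2G42220, AT5G48490, PRK and ATPC1 held in 1, those of LEA18, PAP85 and PSAN in 2 and that of MSRB6 in 4, while AT1G04560, AT3G17520, AT3G54940 and OLEO3 were called in all 8. With the replicate number as a block it was 2799. The split by direction moved as well: 131 were higher and 168 lower after cyclic loess, 154 and 105 without dim probe sets, 32 and 1 with only the 4 arrays, 154 and 234 without wild type on ABA replicate 1, 63 and 17 without replicate 2, and 1358 and 1441 with the block.

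The second comparison asked how ahg1-1 seedlings differed from wild type on the same ABA medium. By limma 0 probe sets passed the adjusted threshold, with a lowest adjusted p of 0.61. Below an unadjusted p of 0.05 lay 326, where exact p-values would give 1112 by chance. Shifts between the numbers tend to make these p-values too large, so a count below 1112 does not mean a difference smaller than chance. With the replicate number as a block 1917 lay below an unadjusted p of 0.05. With it 3 passed, AT5G07360, PDF2.1 and 253894_at (limma, adjusted p = 0.035 for each). The genes named next were chosen after their values were seen and none passed without the block. AT3G56350, which encodes a superoxide dismutase of the iron and manganese family, stood at 8.70 ± 0.79 in ahg1-1 and 5.91 ± 0.57 in wild type (log2, mean ± SD, n = 2), a difference of 2.79 ± 0.47 (SE). The LEA genes AT3G22490 and AT3G53040 differed by 2.71 ± 0.72 and 2.43 ± 0.51, the defensin gene PDF2.1 by 2.37 ± 0.29, AT5G45690 by 2.28 ± 0.35 and the amidase gene AT5G07360 by 2.15 ± 0.29. Several of these differences were nearly equal in both replicate numbers: 2.39 and 2.35 for PDF2.1, 2.12 and 2.17 for AT5G07360, and 2.42 and 2.44 for AT3G53040. Values were lower in ahg1-1 for AT4G23670, of the Bet v 1 family, by -2.37 ± 0.83, for the photosystem genes PSAE-1 and PSBY by -2.24 ± 0.82 and -1.92 ± 0.57, and for the protochlorophyllide reductase PORB by -1.84 ± 0.93. Among probe sets unnamed here, 248125_at differed by 5.02 ± 1.12, 253904_at by 4.40 ± 0.52 and 253894_at by 4.01 ± 0.40. In wild type on ABA 253894_at lay near the lowest values of the arrays, so the size of its difference is uncertain.

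As lists, LEA, storage and oil body genes had higher medians and photosynthesis and cell wall loosening genes lower ones in ahg1-1 than in wild type, calls that held by camera only with a preset correlation. With an estimated correlation the adjusted p = 0.18 for LEA, storage and photosynthesis, and the adjusted p = 0.49 for the cell wall list. The 16 LEA members had a median difference of 0.83, at 1.18 within number 1 and 0.60 within number 2, and 15 of them were higher in both numbers. The 9 photosynthesis members had a median of -1.65, at -2.36 and -0.98, and 8 were lower in both. The 3 storage and oil body genes had a median of 0.91, at 1.38 and 0.64, and the 10 cell wall loosening genes one of -0.23, at 0.00063 and -0.32. Over all probe sets 0 members of these lists passed by limma; adjusted over the list alone, 1 LEA gene was higher, and with the block 8 LEA and 3 storage and oil body genes were higher and 8 photosynthesis genes lower. Camera with a preset correlation gave adjusted p-values of 2.2e-11 for LEA, 1.2e-13 for photosynthesis, 0.00018 for storage and oil body and 0.018 for the cell wall list. COR15A (0.49 ± 0.29), GID1B (-0.65 ± 0.53), ICL (-0.21 ± 0.32), EEL (0.52 ± 0.43), AUR1 (-0.25 ± 0.28), EXPA7 (-0.57 ± 1.04) and BAN (-0.27 ± 0.38) did not pass. Each had the smallest p among the few measured members of its list, and EEL and BAN were the only ones measured in theirs. BAN stood at -0.61 within number 1 and 0.08 within number 2. The lists of stress genes, gibberellin genes and fatty acid breakdown genes did not pass either (camera, adjusted p = 0.97, 0.34 and 0.53). Without wild type on ABA replicate 1 the medians came to 0.22 for LEA, -0.59 for photosynthesis and 0.13 for storage and oil body, the last with a lost call (camera, adjusted p = 0.17). The cell wall list lost its call and turned higher in 2 of the 8 fits without 1 array, to 0.09 without wild type on ABA replicate 1 and 0.15 without ahg1-1 replicate 2 (camera, adjusted p up to 0.78).

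**Figure D2:**
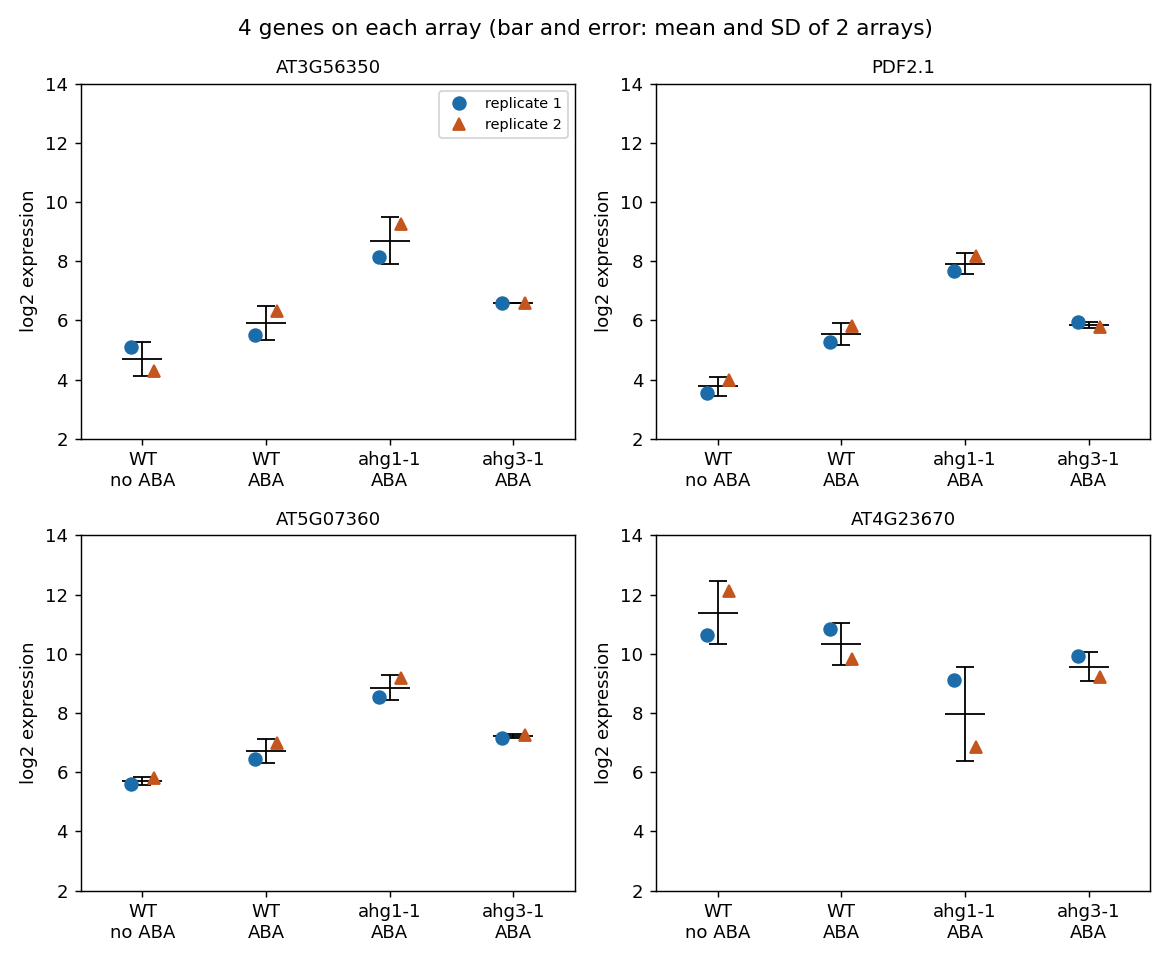
Log2 expression (vertical axis) of 4 genes on each of the 8 arrays, by group, with replicate 1 as circles, replicate 2 as triangles, and the mean and SD of the 2 arrays as a bar with an error bar. Both ahg1-1 arrays lie above the other arrays for AT3G56350, PDF2.1 and AT5G07360 and below them for AT4G23670. The genes were chosen after their values were seen, among those without overlap between the arrays of ahg1-1 and wild type on ABA. Their separation from wild type on ABA therefore follows from the choice. None of these 4 differences between ahg1-1 and wild type on ABA passed the test over all probe sets without the replicate block.

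The third comparison set ahg3-1 against wild type on ABA. By limma 0 probe sets passed, with a lowest adjusted p of 0.99995. Below an unadjusted p of 0.05 lay 18, or 982 with the replicate number as a block, where exact p-values would give 1112 by chance. Without the block the p-values tend to be too large, so the 18 does not mean a difference smaller than chance. With the block 0 passed as well. LEA genes had a median difference of 0.65, and 12 of 16 were higher within both numbers; photosynthesis genes had one of -1.27, and all 9 were lower within both. The medians were 1.24 and -2.16 within number 1 but 0.14 and -0.25 within number 2. AT3G22490, with the smallest p among LEA genes, stood at 8.99 ± 0.11 in ahg3-1 and 7.53 ± 1.56 in wild type, and PSAN at 5.37 ± 0.17 and 6.92 ± 1.53 (n = 2). Named after their values were seen, the unnamed probe set 253904_at differed by 1.77 ± 0.52, the AP2-type factor AT1G72570 differed by 1.01 ± 0.47, the dehydrin gene AT4G39130 by 1.01 ± 0.54 and AT2G24580 by -0.87 ± 0.39, none of which passed.

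The 3 storage and oil body genes had a median of 0.87 in ahg3-1, at 1.61 within number 1 and 0.14 within number 2. The camera test with a preset correlation gave adjusted p-values of 1.3e-08 for LEA, 1.2e-09 for photosynthesis and 0.00033 for storage and oil body, and an estimated correlation gave an adjusted p = 0.26 for each. Stress genes (median -0.13), gibberellin receptors (-0.15), cell wall loosening genes (-0.01) and fatty acid breakdown genes (-0.06, with a mean of 0.02) had adjusted p-values between 0.25 and 0.98. COR47 (-0.79 ± 0.58), GID1B (-0.77 ± 0.53), XTH33 (0.29 ± 0.18), AIM1 (0.21 ± 0.45), EEL (0.50 ± 0.43), PRL (0.29 ± 0.46), EXPA7 (-1.22 ± 1.04) and BAN (-0.08 ± 0.38) did not pass. Without wild type on ABA replicate 1 the 3 preset calls were lost, with medians of -0.11 for LEA, -0.01 for photosynthesis and 0.04 for storage and oil body.

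The fourth comparison set the mutants against each other and tested whether their effects differed. By limma 0 probe sets passed, with a lowest adjusted p of 0.63. Below an unadjusted p of 0.05 lay 92, or 580 with the replicate number as a block, where exact p-values would give 1112 by chance. Without the block the p-values tend to be too large here as well. With the block only 253894_at passed (limma, adjusted p = 0.044). The probe set 253894_at, unnamed here and chosen after its values were seen, stood at 6.97 ± 0.87 in ahg1-1 and 2.97 ± 0.14 in ahg3-1, a difference of 4.00 ± 0.40. The ahg3-1 value lay near the lowest values on those arrays (2.50 and 2.38) and differed from wild type on ABA by 0.012. The size of its differences is therefore uncertain. AT3G56350 was 2.11 ± 0.47 higher in ahg1-1, PDF2.1 2.06 ± 0.29 and AT5G07360 1.65 ± 0.29, while the jacalin-type lectin AT5G35940 differed by -1.43 ± 0.28 and AT5G54370 by -1.45 ± 0.34; these were also chosen afterwards and did not pass. The photosynthesis list had a median of -0.50 in ahg1-1 minus ahg3-1, at -0.37 within number 1 and -0.60 within number 2, the LEA list one of 0.12, at -0.06 and 0.35, and the cell wall list one of -0.14, at 0.09 and -0.34. Camera gave adjusted p-values of 0.00072, 0.0036 and 0.0090 with a preset correlation, and an adjusted p = 0.62 for each with an estimated one. The other 4 lists had adjusted p-values between 0.33 and 0.91. AT3G53040 (1.64 ± 0.51), ATPC1 (-0.50 ± 0.25), XTH19 (-0.57 ± 0.30), COR15A (0.62 ± 0.29), OLEO3 (0.46 ± 0.30), GID1B (0.11 ± 0.53), AIM1 (-0.16 ± 0.45), EEL (0.02 ± 0.43), AUR1 (-0.27 ± 0.28), EXPA18 (0.75 ± 1.08) and BAN (-0.19 ± 0.38) did not pass; the sign differed between numbers 1 and 2 for GID1B (0.29 and -0.06), EEL (-0.06 and 0.09) and BAN (-0.60 and 0.22). Without ahg1-1 replicate 2 none of the 3 preset calls held, with medians of -0.05 for photosynthesis, -0.23 for LEA and 0.27 for the cell wall list, and without ahg3-1 replicate 1 none held either, at -0.19, -0.06 and -0.01.

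Most genes that ABA moved in wild type lay further in the same direction in the mutants, though in ahg3-1 by little within number 2. Of the 154 probe sets that rose with ABA, 130 were higher in ahg1-1 than in wild type on ABA within both replicate numbers and 115 in ahg3-1, or 84.4% and 74.7%, against 31.3% and 30.8% of all probe sets. Of the 151 that fell, 105 were lower in ahg1-1 within both numbers and 91 in ahg3-1, or 69.5% and 60.3%, against 25.2% and 29.0%. The median difference of the 154 was 0.69 within number 1 and 0.41 within number 2 in ahg1-1, and 0.66 and 0.10 in ahg3-1. That of the 151 was -0.49 and -0.16 in ahg1-1, and -0.44 and -0.07 in ahg3-1. Within number 2 alone 119 of the 154 were higher and 95 of the 151 lower in ahg3-1. These comparisons share the wild-type arrays on ABA with opposite signs, which pushes chance values apart. Across all probe sets, which are not independent replicates, the covariance of the ABA change was 0.121 with the ahg1-1 difference (r = 0.55) and 0.093 with the ahg3-1 difference (r = 0.51), where simulated data with no effect gave -0.098 for each. With changes taken from separate arrays the covariance was 0.044 and 0.253 for ahg1-1 and 0.020 and 0.251 for ahg3-1, the first of each pair with the ABA change from number 1. It was -0.048 for ahg1-1 and -0.069 for ahg3-1 without wild type on ABA replicate 1, and 0.0015 and -0.034 without replicate 2. With the 1 shared array then left, simulated data with no effect gave -0.195 and -0.196 without replicate 1 and -0.197 for each mutant without replicate 2, below the observed values. With the spread left after the replicate block they gave -0.063 to -0.062, and the ahg3-1 value without replicate 1 was below that.

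The ahg1-1 and ahg3-1 differences from wild type had a covariance of 0.067 (r = 0.76), at 0.182 within number 1 and 0.019 within number 2. Without 1 array it ran from 0.023, without ahg1-1 replicate 2, to 0.366, without wild type on ABA replicate 2. Both use the same wild-type arrays. Simulated data with no effect gave 0.098, above the observed value, when the spread was taken without the replicate number. With the number as a block they gave 0.031, with a highest value of 0.035, below the observed value. That order turned without wild type on ABA replicate 1 (0.056 observed, 0.063 simulated) and without ahg1-1 replicate 2 (0.023 and 0.031). It turned in no other fit without 1 array. The simulated probe sets were independent, so these values do not decide whether the covariance exceeded chance. With separate arrays it was 0.025 (r = 0.31) and 0.040 (r = 0.28). With 0 calls in each mutant there was no overlap of calls to count.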

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

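These results were noted because a test of the difference between ahg1-1 and ahg3-1 passed its threshold with a preset correlation between genes: the difference in ahg1-1 minus that in ahg3-1 had a median of -0.50 for photosynthesis genes, 0.12 for LEA proteins and -0.14 for expansins and xyloglucan endotransglucosylases. With an estimated correlation each had an adjusted p = 0.62. Of the tests below, that of a single array and that of array-wide scaling were both chosen before their results were seen.

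The median differences of the photosynthesis and LEA lists lay in the direction of the wild-type ABA change. Across probe sets the ahg1-1 minus ahg3-1 difference correlated with that change, with which it shares no array, at r = 0.20. The LEA median was -0.06 within number 1, however, and 6 of 16 LEA members were higher in ahg1-1 within both numbers, with 1 lower. Of 9 photosynthesis members 6 were lower within both numbers and 1 was higher. Whether the cell wall list lay in that direction is not settled, since its median change with ABA was -0.07 with members on both sides. EXPA9, chosen after its values were seen, was higher with ABA (1.49) and lower in ahg1-1 than in ahg3-1 (-0.42). XTH19 was lower with ABA (8.54, against 9.06 without) and also lower in ahg1-1 than in ahg3-1 (-0.57). The agreement over all members was not tested. After cyclic loess r was 0.22, but this says little about array-wide scaling. RMA had already quantile-normalized the arrays, so loess could change little, and scaling before that step was not tested. A single array standing apart stays open, since r was 0.24 within number 2 but only 0.046 within number 1, and the preset calls of the 3 lists were lost without ahg1-1 replicate 2 or without ahg3-1 replicate 1. A difference between the 2 mutations may contribute as well and was not tested apart from this.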

How the results depend on the processing

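Alternatives were planned before the data were examined, except the within-number values, the separate-array covariances, the simulated covariances without 1 array and the replicate block with an estimated correlation. Of the called counts, 0 stayed 0 for the mutants in every alternative but the block. The replicate number shares no stated batch or day, but same-numbered arrays deviated together (r from 0.50 to 0.84). With the replicate block the ABA count was 2799 (1358 higher, 1441 lower), holding all 305 calls; it was 3 for ahg1-1 (AT5G07360, PDF2.1 and 253894_at, adjusted p = 0.035), 0 for ahg3-1 and 1 for ahg1-1 against ahg3-1 (253894_at, adjusted p = 0.044), and no preset list call changed. Over all probe sets the block also called 15 of 16 LEA genes, all 9 photosynthesis genes and 8 of 10 cell wall genes with ABA, as well as EEL and COR15A. The ABA count was 33 with only the 4 arrays compared (fewer samples), 180 with only probe sets of 1 gene (fewer probe sets), and from 51 to 388 leaving out 1 array; an intensity trend, the filter, cyclic loess, centring and the 2-fold minimum gave 259 to 305, with 131 higher and 168 lower after loess and 154 and 105 after the filter. Of 18 named called genes 4 (AT1G04560, AT3G17520, AT3G54940 and OLEO3) were called in each of the 8 fits without 1 array, and 10 in at most 4; in such fits the lone array of a group is assumed to vary like the other groups.

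The covariance of ABA and ahg1-1 changes was 0.191 without dim probe sets, 0.094 with 1-gene probe sets, 0.044 and 0.253 with separate arrays, and from -0.048 to 0.170 without 1 array. That of ABA and ahg3-1 was 0.143 without dim probe sets, 0.020 and 0.251 with separate arrays, and from -0.069 to 0.130 without 1 array. That of the mutants ran from 0.023 to 0.366 without 1 array. Without a wild-type array on ABA simulated data with no effect moved as well, to between -0.197 and -0.195 for the first 2 covariances and to 0.196 and 0.197 for the mutants; other causes were not tested. With the smaller spread left after the replicate block, simulated data with no effect gave 0.031 for the mutants' covariance, now below the observed 0.067, and -0.031 for the others. The mutants' covariance was below the simulated value instead without wild type on ABA replicate 1 (0.056 and 0.063) and without ahg1-1 replicate 2 (0.023 and 0.031). In the other fits without 1 array it stayed above. Without 1 array the list medians ran from -4.82 to -2.06 for photosynthesis and 4.80 to 6.20 for LEA with ABA, from -0.80 to 0.15 for the cell wall list in ahg1-1, from -0.11 to 1.35 for LEA in ahg3-1, and from -0.23 to 0.58 for LEA and -0.47 to 0.27 for the cell wall list between the mutants. An estimated correlation ended all 13 preset list calls, with or without the block. Lists left with fewer than 3 members by the filter on dim probe sets have no value there. Signal over background is not given by these values.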

Other observations

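Genes of the plastid genome were examined as a group chosen after the annotation was seen, together with 39 families of genes that share a symbol. The 69 measured plastid genes had a median log2 change of -0.99 with ABA in wild type, at -1.11 within number 1 and -0.98 within number 2, and 57 were lower within both numbers (limma camera, adjusted p = 2.8e-13 with a preset correlation; adjusted p = 0.89 with an estimated correlation). Their median was -0.27 in ahg1-1 and -0.15 in ahg3-1 against wild type on ABA, at -0.47 and -0.31 within number 1 but -0.07 and -0.05 within number 2, with 35 and 28 lower within both numbers (adjusted p = 7.8e-06 and 0.017 with a preset correlation; adjusted p = 0.81 and 0.85 with an estimated one). The nuclear genes of the photosynthesis list and the plastid genes went opposite ways between the replicate numbers. On number 2 the plastid genes were higher than on number 1 in all 4 groups, by medians of 0.74 in wild type without ABA, 0.79 in wild type with ABA, 1.28 in ahg1-1 and 1.08 in ahg3-1. The nuclear photosynthesis genes differed by -0.55, -2.17, -0.88 and -0.63 in the same order, and LEA genes by 0.40, 1.46, 0.91 and 0.39.

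Of these 40 groups 5 passed with a preset correlation in the ABA contrast, 8 in ahg1-1, 4 in ahg3-1 and 4 between the mutants, and 0 passed with an estimated correlation in any contrast. The 19 GH genes had a median of -0.20 in ahg1-1 against wild type, at -0.36 and -0.08 within numbers 1 and 2, and 11 were lower within both numbers (adjusted p = 0.0010; adjusted p = 0.81 with an estimated correlation). The 6 measured LSM genes, for proteins that bind RNA in splicing and decay, had medians of 0.35 in ahg1-1, at 0.59 and 0.17 within the numbers, and 0.22 in ahg3-1, at 0.30 and 0.24, against wild type on ABA. The 6 NRPB genes, for subunits of RNA polymerase II, had medians of 0.35, at 0.51 and 0.20, and 0.29, at 0.30 and 0.27, and all 6 were higher in ahg3-1 within both numbers. The 11 GSTU genes, for glutathione transferases, had medians of -0.17 in ahg1-1 against wild type, at -0.18 and -0.30, and -0.19 against ahg3-1, at -0.27 and -0.10. Camera with a preset correlation gave adjusted p-values between 0.0036 and 0.017 for the LSM, NRPB and GSTU families in these contrasts. With an estimated correlation the adjusted p = 0.49 for each in ahg1-1, 0.85 for LSM and NRPB in ahg3-1 and 0.47 for GSTU between the mutants.

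Of the tests in the next paragraphs, those of progress along the ABA change, of a number effect with and without ABA, of shared arrays and of wild-type ABA replicate 1 were chosen only after related results were seen. With the replicate number in the fit, 8385 probe sets differed between numbers 1 and 2 by limma at an adjusted p below 0.05, 4520 higher in number 2 and 3865 higher in number 1. After cyclic loess 7938 probe sets still differed, but this says little about array-wide scaling. RMA had already quantile-normalized the arrays, so loess could change little, and scaling before that step was not tested. In the mutants, different progress along the wild-type ABA change is argued against as the whole cause. That change explained 8.25% of the variance of their number difference over these probe sets. As part of the cause it stays open. The first principal component (63.8% of the variance) was lowest on the arrays without ABA and higher on number 2 in all 4 groups. It went from -102.1 to -64.2 without ABA, -38.6 to 47.8 in wild type on ABA, 15.8 to 67.9 in ahg1-1 and 16.4 to 57.0 in ahg3-1. An effect that acts with and without ABA, such as a shared day, seed batch or stage of growth, is consistent with r = 0.60 across all probe sets between the number differences without ABA and in the mutants; the labels do not say what a number shares, and no biological explanation was tested.

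The mutant differences followed the wild-type ABA change. Chance values of the shared wild-type arrays were examined with separate arrays, where the lowest r of the 4 pairings was 0.18. Without a known chance range of r this does not decide whether chance contributes. Wild-type ABA replicate 1 was examined through part of the same pairings, so this is no second test. The mutant differences within number 2, which do not use it, gave r of 0.22 and 0.18 with the ABA change within number 1, which does. Those covariances were 0.044 and 0.020, against 0.253 and 0.251 with the mutant differences within number 1. No chance range of r is known for correlated probe sets, so how much of the pattern rests on that array stays open. Without that array the ahg3-1 covariance of -0.069 was no higher than the -0.062 of simulated data with the spread left after the replicate block. After cyclic loess 96.6% of the lower covariance remained. The arrays had already been quantile-normalized, so this says little about array-wide scaling. A stronger response of the mutants to ABA may explain the pattern, and so may a difference in the stage of germination between genotypes; mutants without ABA are not analysed here, so these stay open.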
